A study of Homo sapiens with 3 samples.

How the data were processed

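Poly(A)-selected RNA was sequenced from HEK293 cells, an established line derived from human embryonic kidney. Per the labels, the cells were a T-REx Flp-In derivative with a FLAG-tagged DICER1 transgene. T-REx cells carry a tetracycline-regulated expression system, and whether the transgene was switched on is not given in the sources used here. The cells were transfected for RNA interference. The 3 libraries were a DICER1 knockdown, a DROSHA knockdown and a mock transfection, with 1 library in each of the 3 groups. Every title carries the label 2.5d, which the labels do not explain. RNA was extracted with TRIzol and libraries were made with an Illumina TruSeq RNA kit for the HiSeq2000, per the labels' protocols. Whether reads were counted by strand is not given in the sources used here.

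One deposited table covers the whole series. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.06, Cufflinks, Cuffdiff 2.1.1, SAMtools and the genome build hg19, without saying which step each served. The table lists 12040 gene symbols, none repeated, with no header line. Besides the symbol it holds 3 columns of levels, for libraries that it does not name, and 2 columns of log2 fold changes made by the authors. A test on the values found that both fold changes were the log2 ratio of a level to the same denominator level, after 1 had been added to each. The largest deviation was 5e-12, and all 12040 genes lay within a tolerance of 1e-11. The denominator level was above 1 in every gene listed. The numerator level was below 1 in 178 genes in the first fold change and in 298 in the second. Adding 1 shrinks the fold changes of genes with low levels, and genes with a denominator level of 1 or less were not analysed here.

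Because no column carries a name, none could be matched to a knockdown or to the mock transfection from its label, and order and values were not used for this. The 3 level columns served only for the test above. The 2 columns of the authors' deposited log2 fold changes are called the first and the second deposited comparison, in the order of the table, and no knockdown is assigned to either. The planned comparisons of each knockdown with mock transfection, and of the knockdowns with each other, were therefore carried out on the unnamed comparisons. The first minus the second fold change was computed per gene. It equals the log2 ratio of the numerator levels and does not depend on the shared denominator. The depth of each library is unknown, since the table holds no counts.

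With 1 library per group there is no replicate error, no test of the conditions and no p-value, and every value describes these libraries. A gene is said to have risen or fallen where its log2 fold change was at least 1 in size, a 2-fold difference. Genes were named by a rule set before the data were examined. Its floor on the mean level was not applied, since the level columns match no sample's labels, so named genes may have low levels. The rule took DICER1 and DROSHA, and the 12 highest and 12 lowest genes of each deposited comparison. It also took the 8 highest and 8 lowest of the difference, and up to 2 genes at either end of each list. Symbols of annotated miRNA, snoRNA, LINC, LOC and antisense genes were left out of the ranking, and all measured members of the small RNA machinery list were eligible. Other genes named were chosen after their values were seen, and are marked as such.

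The 34 gene lists were written from textbook knowledge before the data were examined. Of these, 27 had at least 5 measured members. The median of each was placed among the medians of 10000 random lists of the same size drawn from all 12040 genes, and the percentile is given. A list counts as outside random lists below percentile 2.5 or above 97.5. Random draws of genes place 1.35 of 27 lists outside per comparison. This holds for genes drawn independently, not for genes that move together, and does not measure variation between libraries. Random lists were not matched on expression, because the level columns match no sample's labels and were not used for it. When lists were drawn at random from the same fold changes, between 4.3% and 6.1% fell outside, a share set by construction. A shift of 0.1 added to such lists put 82.2% of lists of 41 genes outside in the first comparison and 51.3% in the second.

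Sequences came from GENCODE release 29 on GRCh38, a later build than that of the table, and served only to search transcripts. Of the symbols, 10580 matched a protein-coding transcript and 10374 of these had a 3' UTR of at least 50 bases. Fold changes of those genes were adjusted by least squares for transcript length, 3' UTR length and GC content, each with a squared term. The adjusted mean was compared for carriers of each of 16131 7-mers present in the 3' UTR of at least 50 genes, ranked by the mean times the square root of the number of carriers over the spread of all genes (the standardised mean). On shuffled values of the first comparison, a planted shift of -0.05 ranked its 7-mer lowest in 20 of 20 trials. These trials used 7-mers with an intermediate number of carriers. They do not cover 7-mers with few carriers or the second comparison. The genes were also split at random into 2 sets of 5187, and the lowest 7-mer picked in each set was measured in the other. This scan, and the alternatives built on it and on GC content, were added after the data had been seen. Alternatives chosen before the data were examined were other thresholds, re-centring on the median of all genes, and the mean or the share above 0 in place of a list's median. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.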

Results

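The series asked how depletion of DICER1, the enzyme that cuts miRNA precursors and other double-stranded RNA, affects transcript levels in HEK293 cells. A knockdown of DROSHA, which acts one step earlier in miRNA maturation, and a mock transfection were the controls. Poly(A) RNA was sequenced from 1 library of each of the 3 groups. The values are the authors' log2 fold changes for 12040 genes in 2 comparisons with a shared denominator library, and the depth is unknown. The table does not name its columns, so the comparisons are called first and second, and neither is assigned to a knockdown. There were no replicates, so no difference could be set against replicate error.

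DICER1 had the lowest value of the small RNA machinery in the first comparison and DROSHA in the second. In the authors' deposited table DICER1 stood at -1.32 in the first comparison and 0.58 in the second. DROSHA stood at -0.11 in the first and -1.65 in the second in the authors' deposited table. The DICER1 row can also hold reads from the FLAG-tagged transgene. DGCR8, the RNA-binding partner of DROSHA, was listed at 0.17 and 0.54 in the authors' deposited table. Among the 31 measured genes of the machinery, DICER1 alone fell in the first comparison and DROSHA alone in the second, and none rose. The authors' deposited table gave TARBP2, a partner of DICER1, 0.24 and 0.40, and XPO5, which exports miRNA precursors from the nucleus, 0.20 and -0.13. The Argonaute genes in the authors' deposited table were at 0.24 and -0.44 (EIF2C1), -0.13 and -0.44 (EIF2C2), 0.03 and 0.53 (EIF2C3) and -0.40 and 0.10 (EIF2C4). The median of the list was 0.01 in the first comparison (percentile 32.8 among random lists) and -0.04 in the second (percentile 20.4).

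In the first comparison 21 genes rose and 20 fell. The authors' deposited table listed CHGB, the granule protein chromogranin B, at 2.09, SNAP25, a SNARE protein of vesicle fusion, at 1.74, and SYP, synaptophysin, at 1.54. Also in the authors' deposited table, CELSR3 was at 1.61, SCAMP5 at 1.41, the glycine transporter SLC6A9 at 1.40, and CPLX1, complexin, at 1.33. TMEM145 at 1.33, ASPHD1 at 1.31, STMN3 at 1.30, TXNIP at 1.28 and NUPR1 at 1.21 completed the 12 highest in the authors' deposited table. At the other end of the authors' deposited table stood DDAH1 at -1.51, FSTL1 at -1.39, C15orf38 at -1.32, ERLIN2 at -1.30, the autophagy receptor SQSTM1 at -1.27, and CYCS, cytochrome c, at -1.25. ETV5 at -1.25, CHCHD8 at -1.22, FAM18B1 at -1.16, the kinase CHUK at -1.16 and ZFP91 at -1.11 followed in the authors' deposited table. Of the 20 genes that fell, 16 had an annotated 3' UTR, and 14 of these carried CAATCTA or AATCTAA in it (87.5%, against 14.4% of all 10374 genes with one). Both 7-mers were picked because their carriers were lowest in this comparison, so the share is not independent evidence.

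Neuronal marker genes stood furthest from random lists in the first comparison. Of the 15 measured, 5 rose and none fell, and their median of 0.64 lay above all 10000 random lists. Besides CHGB, SNAP25, SYP and STMN3, the neurofilament-related gene INA rose, at 1.05 in the authors' deposited table, and is named here after its value was seen. UCHL1 was the lowest member, at -0.17 in the authors' deposited table. Targets of the integrated stress response and the unfolded protein response had a median of 0.29 over 41 genes, also above all random lists. Only NUPR1 and SESN2 of that list rose, SESN2 at 1.14 in the authors' deposited table, while the chaperones HSPA5 and HSP90B1 were at -0.30 and -0.26 in the authors' deposited table. The 80 genes of cytosolic ribosomal proteins had a median of 0.25, above all random lists, with 77 above 0 and none that rose. RPL13A was the highest of them at 0.65 and RPL21 the lowest at -0.36 in the authors' deposited table.

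Further lists lay outside random lists in the first comparison with smaller medians. The 18 snoRNA host genes had a median of 0.21 (percentile 99.95), with GAS5 at 0.63 and SNHG7 at 0.56 in the authors' deposited table. The 31 p53 targets had a median of 0.17 (percentile 99.94), where SESN2, which is also in the stress list, alone rose and BBC3 was at 0.85 in the authors' deposited table. Genes of cholesterol synthesis had a median of -0.11 over 32 genes (percentile 0.03), and INSIG1 was the lowest at -0.99 in the authors' deposited table. The 24 genes of the interferon response had a median of -0.09 (percentile 0.44), with IFIT1 at -0.52 in the authors' deposited table. That placement ended by the mean (percentile 2.82), by the share above 0 (percentile 7.79) and without genes carrying CAATCTA, AATCTAA, GTGACTT or TGACTTA in the 3' UTR (median -0.02, percentile 10.36). Those of snoRNA hosts and p53 targets ended by the share above 0 (percentiles 96.34 and 94.95). Fold changes were higher at higher GC content across genes, which are not independent replicates (Spearman rho 0.39 over 10374 genes), and random lists were not matched for it.

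**Figure D1:**
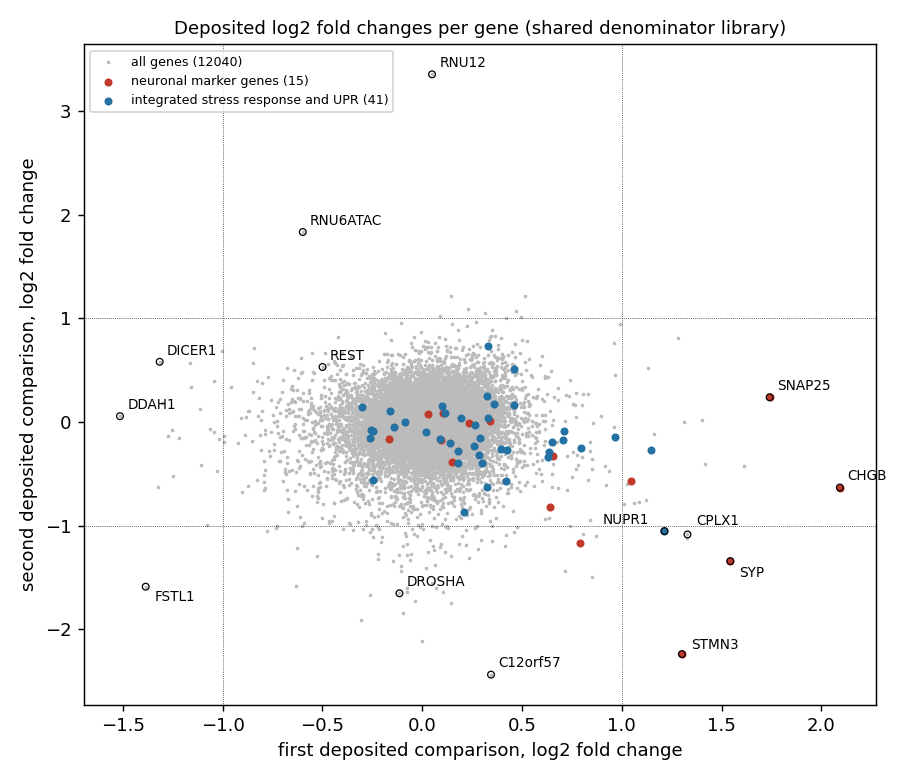
Deposited log2 fold changes of 12040 genes in the first (x axis) and second (y axis) comparison, 1 point per gene, with neuronal marker genes in red and stress response genes in blue; dotted lines mark 1 and -1. Neuronal markers such as STMN3 (1.30 and -2.24) and SYP (1.54 and -1.34) lie to the lower right, and FSTL1 (-1.39 and -1.59) is the only gene beyond -1 on both axes, as listed in the authors' deposited table.

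In the second comparison 10 genes rose and 90 fell. A pair of small nuclear RNAs of the minor spliceosome stood highest, RNU12 at 3.35 and RNU6ATAC at 1.83 in the authors' deposited table. These RNAs are short and carry no poly(A) tail. The authors' deposited table then listed H3F3A, a gene of histone H3.3, at 1.22, SERPINI1, neuroserpin, at 1.22, and CTSA, a lysosomal peptidase, at 1.09. IFI35 was at 1.07, MTRNR2L2 at 1.05, GPR137B at 1.02 and TPRG1L at 1.01 in the authors' deposited table. The next values in the authors' deposited table were 0.97 for the iron exporter SLC40A1, 0.95 for MICA and 0.94 for the splicing regulator PTBP2. Among the genes that fell, the authors' deposited table listed C12orf57 at -2.44, STMN3 at -2.24, PRDX3, a mitochondrial peroxiredoxin, at -2.11, and CORO1C, an actin-binding protein, at -1.91. ZDHHC24 at -1.85, ARL6IP6 at -1.75, SLMO2 at -1.73, OIP5 at -1.67, RRM2, a subunit of ribonucleotide reductase, at -1.64, MRPL45 at -1.64 and SLMO2-ATP5E at -1.61 followed in the authors' deposited table. SLMO2 overlaps its readthrough row, and H3F3A and MTRNR2L2 have near-identical copies, so their values are uncertain. Of the 81 fallen genes with an annotated 3' UTR, 48 carried GTGACTT or TGACTTA in it (59.3%, against 20.8% of all 10374 genes), and these 7-mers too were picked from the values of this comparison.

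Neuronal marker genes were lower than random lists in the second comparison, with a median of -0.33 over 15 genes (percentile 0.03). STMN3, SYP and CRMP1 fell, CRMP1 at -1.17 in the authors' deposited table and named after its value was seen. SNAP25 was the highest member at 0.24 in the authors' deposited table. This placement ended when the share of members above 0 replaced the median (percentile 3.16). Genes of cholesterol synthesis had a median of -0.21 over 32 genes, below all random lists, with FADS2 at -0.88 and SREBF2, a regulator of the pathway, at -0.73 in the authors' deposited table. The 45 genes of the G1/S transition and DNA replication had a median of -0.17 (percentile 0.04), and RRM2 alone fell. CCNE1, cyclin E1, was at -0.79 in the authors' deposited table. The stress response list had a median of -0.16 over 41 genes (percentile 0.06), with NUPR1 at -1.05 and ATF5 at -0.87 in the authors' deposited table. Adjustment for length and GC content ended that placement (median -0.07, percentile 2.75).

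Several groups were higher than random lists in the second comparison. The 58 listed targets of the miR-17 family had a median of 0.17, above all random lists, with 38 above 0. Among the 58, GPR137B alone rose and CDKN1A alone fell, CDKN1A at -1.01 in the authors' deposited table. The 40 targets of miR-19, miR-92, miR-130 and miR-301 had a median of 0.15 (percentile 99.92). Among the 40, ATXN1 was the highest at 0.72 in the authors' deposited table, while HIPK3 alone fell, to -1.05. Without genes carrying the 3' UTR sites above, 27 genes of each list were left, with medians of 0.27 and 0.28. Those sites were picked because their carriers were lowest, so part of each rise is built in. Cytosolic ribosomal proteins had a median of 0.13 over 80 genes (percentile 99.98), led by RPL13A at 0.49 in the authors' deposited table. For 400 zinc finger genes the median was 0.11, above all random lists, with 269 above 0 and only ZNF395 fallen, at -1.31 in the authors' deposited table. The 47 G2/M genes had a median of 0.11 (percentile 99.13), with ANLN at 0.55 and NUF2 at 0.49 in the authors' deposited table, and adjustment for length and GC content ended that placement (percentile 94.96). Fold changes were lower at higher GC content across genes here (Spearman rho -0.28).

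The medians of targets of other miRNAs lay within random lists in both comparisons. The 41 let-7 targets had medians of 0.06 and 0.10 (percentiles 77.5 and 97.4). In the second comparison they lay outside by the share above 0 (percentile 98.62) and after adjustment for length and GC content (percentile 97.78). They stayed within by the mean (0.0023, percentile 67.62) and without genes carrying the 3' UTR sites above (percentile 90.34). RRM2 and E2F5 fell in that comparison, E2F5 at -1.21 in the authors' deposited table. The 43 targets of miR-15 and miR-16 had medians of -0.0020 and 0.05 (percentiles 18.4 and 85.8). For 33 targets of miR-10 and other miRNAs found in HEK293 the medians were 0.05 and 0.08 (percentiles 72.7 and 91.9), with PTBP2 at 0.99 and 0.94 in the authors' deposited table. In the first comparison the targets of the miR-17 family had a median of 0.06 (percentile 86.5) and those of miR-19, miR-92, miR-130 and miR-301 a median of 0.07 (percentile 89.9). Adjustment placed the miR-17 list outside (percentile 99.41) but not the other list (percentile 97.31). Removal of genes carrying the 3' UTR sites above, which left 27 genes of each, placed both outside (percentiles 98.04 and 99.72). Those sites were picked because their carriers were lowest, so part of this is built in. By the mean, the miR-17 list stayed within (percentile 94.04). The list of miR-19, miR-92, miR-130 and miR-301 targets, which includes DICER1, had a mean of -0.0125 (percentile 16.08). TXNIP, a listed target of the miR-17 family, was at 1.28 and 0.81 in the authors' deposited table.

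**Figure D2:**
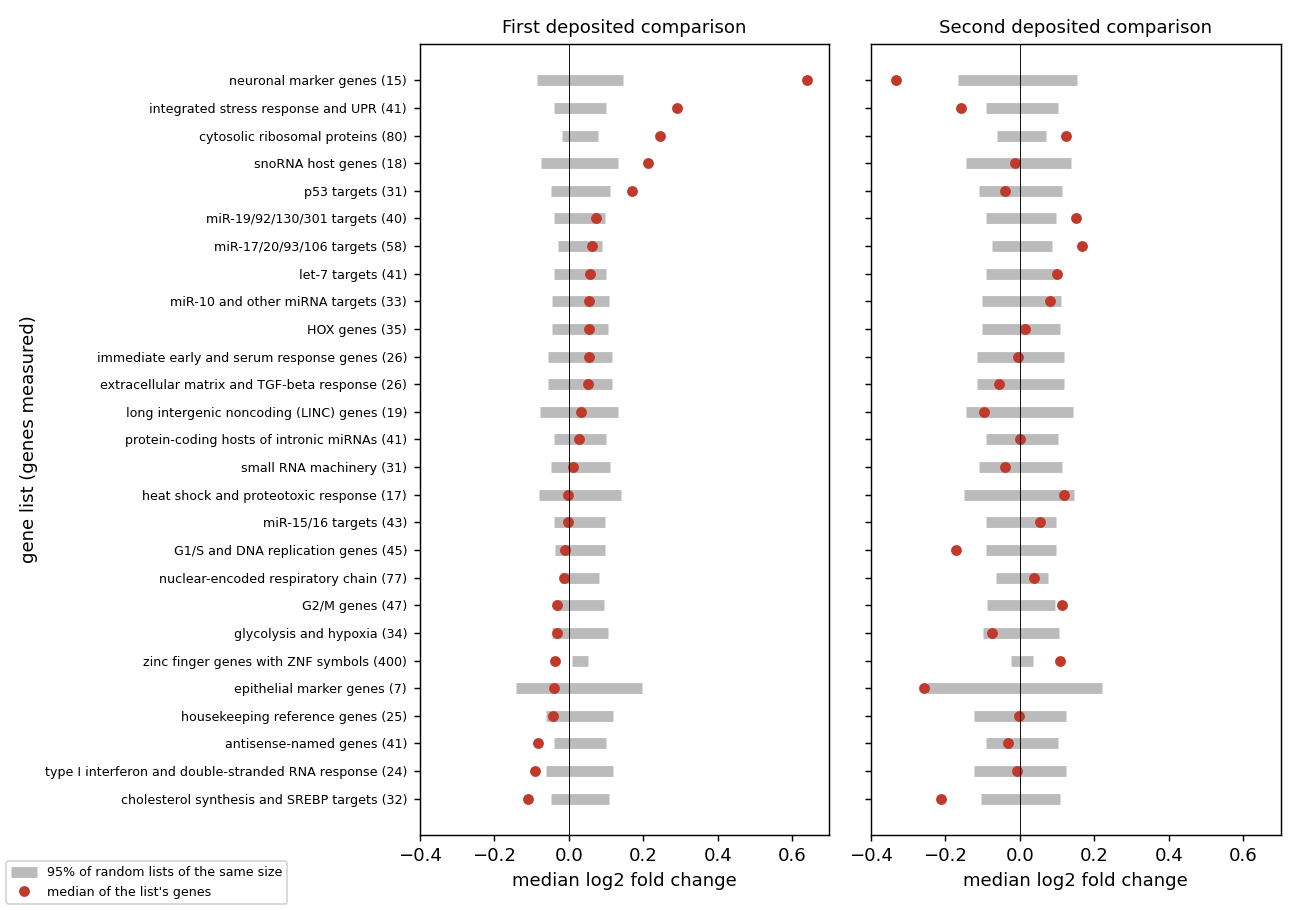
Median log2 fold change (x axis) of the 27 gene lists with at least 5 measured genes (y axis, number of genes in brackets) in the first (left) and second (right) deposited comparison; points are list medians and grey bars span 95% of random lists of the same size. Neuronal marker genes lie at 0.64 on the left and -0.33 on the right, and the 2 panels place 9 and 10 lists outside random lists.

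The first minus the second fold change compares the numerator libraries directly, and 158 genes stood at 1 or more and 42 at -1 or less. STMN3 had the highest difference, 3.54, followed by SYP at 2.89, C12orf57 at 2.78, CHGB at 2.72, TMEM145 at 2.44, CPLX1 at 2.41, P2RY11 at 2.34 and NUPR1 at 2.27. RNU12 was lowest at -3.31, then RNU6ATAC at -2.43, DICER1 at -1.90, FAM18B1 at -1.73, CMPK1 at -1.69, DDAH1 at -1.57, CREBL2 at -1.55 and CHUK at -1.50. DROSHA differed by 1.54. Of the lists, 9 lay outside random lists. The difference had a median of 0.99 for neuronal marker genes and 0.34 for stress response genes, both above all random lists, 0.21 for p53 targets (percentile 99.63), 0.16 for G1/S genes (percentile 99.15) and 0.14 for ribosomal proteins (percentile 99.62). It had a median of -0.17 for G2/M genes and -0.14 for zinc finger genes, both below all random lists, -0.13 for targets of the miR-17 family (percentile 0.05) and -0.10 for those of miR-19, miR-92, miR-130 and miR-301 (percentile 1.39). Adjustment for length and GC content ended the placements of the last list (median -0.08, percentile 11.07) and of G2/M genes (median -0.11, percentile 2.72). Without genes carrying the 3' UTR sites above, the median of zinc finger genes was -0.09, still below all random lists. The placement of p53 targets ended by the share above 0 (percentile 94.3), and that of G1/S genes without those carrying the sites (percentile 96.28). The difference was higher at higher GC content across genes (Spearman rho 0.47 over 10374 genes), more strongly than either comparison. Random lists were not matched for it, and the ribosomal protein list could not be adjusted.

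The fold changes of the 2 comparisons were weakly related across the 12040 genes (Pearson r 0.06, Spearman rho 0.07), and genes are not independent replicates. Independent libraries of equal noise with a shared denominator gave r = 0.5 in 100 simulations. The covariance was 0.00408, against 0.0258 in the simulation, whose noise was set from the spread of the first comparison. FSTL1, at -1.39 and -1.59 in the authors' deposited table, was the 1 gene that fell in both, where independent lists give 0.15. No gene rose in both, where independent lists give 0.0174. The simulation gave 0 for both counts, but its normal noise, with the spread of the first comparison (SD 0.227), rarely reaches 1. Those counts of 0 were therefore set by its setting and cannot be compared with the data. Part of any overlap may come from the shared denominator library, which could not be split. CPLX1, NUPR1, STMN3, SYP and TMEM145 rose in the first comparison and fell in the second.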

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

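The lists were fixed before the data were examined. Of the tests on neuronal genes, the adjustment for GC content and length was chosen before its result was seen, and the check with the shared library cancelled and the search for REST were chosen afterwards. A list was picked out here where its medians lay outside random lists on opposite sides in the 2 comparisons, and the difference itself was not tested, since each group has 1 library. The median of the first minus the second fold change was 0.987 for neuronal marker genes, 0.335 for stress response genes and -0.144 for zinc finger genes.

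Neuronal marker genes were higher in the first comparison and lower in the second (medians 0.64 and -0.332). The shared denominator library as the whole cause is argued against by the median of the difference, in which that library cancels: it was 0.987, against -0.161 to 0.216 for 95% of random lists, while picking lists on opposite sides asks for a gap of 0.312 between their medians. GC content and transcript length do not account for the first comparison either, since the adjusted median was 0.502, against -0.0978 to 0.110 for 95% of random lists. A candidate explanation is the level of REST, a repressor of neuronal genes, which was at -0.499 in the first comparison and 0.53 in the second in the authors' deposited table, opposite to the list in both. This rests on 1 gene in single libraries, REST protein was not measured here, and a difference between the cultures unrelated to either knockdown remains open.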

How the results depend on the processing

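The thresholds, re-centring, mean, share and restriction to changed genes were planned; the adjustment for length and GC content and the removal of genes with a seed-like site (CAATCTA, AATCTAA, GTGACTT or TGACTTA in the 3' UTR, 3038 genes) were chosen after the data were seen. At the main threshold 0.174% of 12040 genes rose and 0.166% fell in the first comparison, 0.0831% and 0.748% in the second, and 1.31% and 0.349% in the difference. At 0.6 these were 0.831% and 1.19%, 1.10% and 3.59%, and 5.81% and 2.68%, and at 1.5 they were 0.0332% and 0.00831%, 0.0166% and 0.133%, and 0.357% and 0.0581%. Re-centring kept each count within 1.5 times. By more than 1 SD of random lists it moved the first comparison's medians of miR-17 targets from 0.0625 to 0.0321, of ribosomal proteins from 0.246 to 0.215, of the respiratory chain from -0.0134 to -0.0438 and of zinc finger genes from -0.0377 to -0.0680, and the difference's median of zinc finger genes from -0.144 to -0.169. The first comparison's medians of the small RNA machinery (0.0127) and of intronic miRNA hosts (0.0277) turned to -0.0176 and -0.00261, and in the difference those of HOX genes (0.0188), LINC genes (0.0104) and miR-15 and miR-16 targets (0.0138) turned to -0.00583, -0.0142 and -0.0108, all within random lists. Other medians, such as those of let-7 targets (0.0560 to 0.0256), G1/S (-0.0106 to -0.0409) and G2/M genes (-0.0303 to -0.0607) in the first comparison, moved by less than 1 SD. Without genes with a seed-like site, 5 genes fell in the first comparison (0.0555% of 9002), 39 in the second (0.433%) and 14 in the difference (0.156%), where 92 rose (1.02%) in place of 158. The 9002 include genes whose 3' UTR was not searched and may hold a site. Of the genes that fell, 16 of 20 in the first comparison and 81 of 90 in the second were searched. The sites were picked from these values, so part of the drop is built in. The correlation between the comparisons reversed to -0.0654 over the 135 genes that rose or fell in either, and the cause was not tested; it was 0.144 after adjustment and 0.0888 without seed-like sites.

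Of the 9 lists outside random lists in the first comparison, 8 stayed so by the mean, 6 by the share above 0 and 8 without seed-like sites. Of the 10 in the second, 10, 8 and 9 did. In the first, removal left snoRNA hosts and antisense-named genes whole, so it did not test these 2 of the 8. Adjustment could be checked for 22 lists with sequences for at least 80% of members. It kept 6, ended 0 and placed 2 more outside in the first comparison (miR-17 targets and glycolysis genes), and kept 7, ended 2 and placed 2 more outside in the second (let-7 targets and HOX genes). In the difference it kept 6 and ended 2. It was void for the small RNA machinery (77.4% covered), ribosomal proteins (77.5%), snoRNA hosts (11.1%), and LINC and antisense-named genes (0% each). In the difference, other settings placed outside random lists let-7 targets by the share (percentile 1.72), interferon genes by the mean (1.2), snoRNA hosts by both (99.91 and 98.01) and intronic miRNA hosts without seed-like sites (99.06). Other pseudocounts, floors and lists matched on expression were not run, since the level columns match no sample's labels. Counting every row changes nothing without repeated symbols, and no fold change was infinite. No paired analysis was possible with 1 library per group. Depth is unknown, and genes with low levels were not separated from well-measured ones.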

Other observations

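The scan of 16131 7-mers in 3 comparisons was made after the data were seen, as were the tests of base composition, the shared library, 3' UTR against coding sequence in split genes, the miRNA families and sites in single genes. Some further lists had medians within random lists, with few genes past the threshold. The 35 HOX genes had medians of 0.05 and 0.01 (percentiles 73.8 and 56.0; the second was 97.88 after adjustment for length and GC content), with HOXA5 at 0.56 in the first comparison and HOXC8 at 0.64 in the second in the authors' deposited table. The 17 heat shock genes had a median of 0.12 in the second comparison (percentile 94.2) and -0.00097 in the first (percentile 28.4). Glycolysis and hypoxia genes had medians of -0.03 and -0.07 over 34 genes (percentiles 5.18 and 6.73), and the nuclear-encoded respiratory chain -0.01 and 0.04 over 77 genes (percentiles 4.36 and 81.6). Glycolysis and hypoxia genes lay outside after adjustment in the first comparison (percentile 0.24) and without genes with a seed-like site in the second (percentile 1.95), and the respiratory chain without such genes in the first (percentile 0.93). Genes listed as hosts of intronic miRNAs had medians of 0.03 and -0.00076 over 41 genes (percentiles 46.9 and 43.2), with FSTL1 the 1 listed gene that fell in either. Whether the miRNA of FSTL1 lies in an intron was not checked. Immediate early genes had medians of 0.05 and -0.0057 over 26 genes (percentiles 71.3 and 41.9). Extracellular matrix and TGF-beta response genes had medians of 0.05 and -0.06 over 26 genes (percentiles 68.8 and 14.8), and ID1 and ID3, inhibitors of helix-loop-helix transcription factors, fell in the second comparison to -1.19 and -1.30 in the authors' deposited table. The 25 housekeeping genes had medians of -0.04 and -0.0033 (percentiles 5.63 and 43.5).

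The 400 zinc finger genes had a median of -0.04 in the first comparison, below all random lists, and none rose or fell there. Without genes with a seed-like site it was -0.00347, still below all random lists. The 41 antisense-named genes had a median of -0.08 in the first comparison (percentile 0.04) and -0.03 in the second (percentile 21.6), and DICER1-AS was the lowest in both, at -0.90 and -0.68 in the authors' deposited table. Antisense rows are uncertain, since counting by strand is not stated. LINC genes had medians of 0.03 and -0.10 over 19 genes (percentiles 51.9 and 7.78). In the second comparison the medians were -0.01 for snoRNA hosts (percentile 39.9), -0.04 for p53 targets (percentile 19.8) and -0.0064 for interferon response genes (percentile 41.4). In the first they were -0.01 for G1/S genes (percentile 11.3) and -0.03 for G2/M genes (percentile 3.57, and 0.03 by the mean of the members). The 7 epithelial markers had medians of -0.04 and -0.26 (percentiles 20.9 and 2.08), and KRT19 fell in the second comparison, at -1.07 in the authors' deposited table. The second placement ended by the share above 0 (percentile 13.54) and without genes with a seed-like site (percentile 5.92), and the first lay outside by the share above 0 (percentile 1.57). Of 4 blood markers, HBA1 rose in the first comparison, at 1.16 in the authors' deposited table, and the endothelial markers ESAM and EGFL7 were at -0.52 and -0.04 there. The miRNA host transcripts DLEU1, DLEU2 and MGC16121 were at -0.23, 0.25 and 0.39 in the first comparison of the authors' deposited table and at 0.26, 0.47 and -0.22 in the second. Replication-dependent histones, mitochondrially encoded transcripts, miRNA rows and snoRNA rows had 0 measured members.

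Genes with AATCTAA in the 3' UTR had the lowest standardised mean in the first comparison (-0.101 adjusted, 1221 genes) and genes with GTGACTT in the second (-0.145, 1469 genes). Base composition beyond the adjusted GC content is argued against as the whole cause, since it predicts similar means for all orders of the bases. The 102 and 417 orders sharing no 6 bases in a row with the site had median means of -0.000343 and -0.00108 (ranges -0.0182 to 0.0128 and -0.0435 to 0.0725). Orders that share them reached -0.0617 and -0.0787. The adjustment may itself bring such medians towards 0, and picking the lowest 7-mer favours a place outside the range. In genes not used for the pick, 3' UTR carriers still stood at -0.101 and -0.145 on average, below all these orders. The shared library as the whole cause is argued against too. In the difference, where it cancels, carriers stood at -0.0905 and 0.141, outside 95% of random gene sets. Picking the lowest 7-mer by itself moves the difference this way, and random gene sets carry no such pick. The shared library alone would, however, give carriers like means in both comparisons. In the comparison not used for the pick they stood at -0.0105 (AATCTAA, second) and -0.00355 (GTGACTT, first). With the genes split at random into 2 sets, each set picked the same 7-mer, and in the other set its 3' UTR carriers were lower than carriers in the coding sequence alone, by -0.0717 and -0.0965 on average, while the latter (-0.0294 and -0.0481) also lay below 95% of random gene sets except in 1 set of the first comparison. A hypothesis is that the numerator libraries held transfected small RNAs that silence through seeds matching these sites, but the sequences used are not given in the sources used here, and GCCTACT, also low in the second comparison (-0.0959, 578 genes), is not part of the 8-mer GTGACTTA and was not followed up.

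On GRCh38, CAATCTAA, which joins CAATCTA and AATCTAA, occurs in the coding sequence of DICER1, on chromosome 14 from 95116556 to 95116563 on the minus strand, in exon 12 of 29 of the transcript searched. GTGACTTA, which joins GTGACTT and TGACTTA, occurs in the coding sequence of DROSHA, on chromosome 5 from 31511135 to 31511142 on the minus strand, in exon 8 of 35. Such 8-mers also occur in 5.84% and 4.94% of genes with a coding sequence at least as long, and the matches assign no knockdown to a comparison. The 3' UTR of REST, in exon 4 of 4 on chromosome 4, holds CAATCTA from 56933030 to 56933036 and from 56935409 to 56935415, and AATCTAA from 56932334 to 56932340. It also holds 2 copies of GCACTTT, the site of the miR-17 family, and the coding sequence of REST holds 1 AATCTAA. CAATCTA or AATCTAA occurs in the 3' UTR of 14.4% of all 10374 genes. The share among genes with a 3' UTR as long as that of REST (3692 bases) was not computed. Whether any of these sites acts on REST was not tested.

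Genes with GCACTTT, the site of the miR-17 family, in the 3' UTR had the highest standardised mean in the second comparison (0.0352 adjusted, 2423 genes; 0.00745 in the first). In the difference, where the shared library cancels, their mean was -0.0278, against -0.0114 to 0.0115 for 95% of random gene sets. GCACTTT was picked as the highest in the second comparison, which by itself lowers this difference. Random gene sets carry no such pick, so the shared library stays open for this site. Base composition stays open: the 417 orders of its bases sharing no 6 in a row with it had a median mean of -0.000585, but their means ran from -0.0514 to 0.0451, a range that holds the site's. Reduced miRNA function may account for it but could not be settled. After 3 families with listed sites at the top of the scan were dropped, the other 10 families expected in HEK293 had a median of 0.0150. It was above the median of 0.00387 over 6 families not expected there and below the highest of these, 0.0162. The sites TTGCACT (miR-130 and miR-301) and TGTTTAC (miR-30), kept among the 10, share 6 bases in a row with TTTGCAC and GTTTACA. Both of the latter were among the highest of the scan, so the median of 0.0150 is not independent of it. All 13 expected families had a median of 0.0178, against 0.00336 in the first comparison, and a difference between cultures and the effect of the transfected RNA itself remain open.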
